A study of Mus musculus with 8 samples.

How the data were processed

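Stranded mRNA libraries of primary sternal chondrocytes from mouse embryos were compared in 3 groups, per the labels: 3 libraries of Col2a1Cre;Idh1 fl/+ cells, 3 of Col2a1Cre cells and 2 of Idh1 fl/+ cells. Per the labels' protocols, sterna were digested with enzymes, RNA was taken up with a column kit and libraries were made with the KAPA stranded mRNA kit. The design text of the series writes the floxed genotype as fl/fl and the sample labels as fl/+, and the sample labels were followed. Replicates were numbered in the order of their records, so a number pairs no samples, and no batch is given.

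The deposited data are 3 tables, 1 per pair of groups, of the same genes (14711 coding and 1721 non-coding). Per the submitters' processing notes, Trim Galore, cutadapt, STAR, HTSeq and DESeq2 were used. Their versions and the genome build are not given in the sources used here, so no coordinates are printed. The signal analysed is the authors' normalized expression value of each gene in each library, per the file headers, called the normalized count because each library's values are whole multiples of 1 value, as read counts divided by a size factor are. The log2 fold change in each deposited table and its Wald statistic are the authors' own, per the file headers. The p-value and the adjusted p-value in each table are also the authors' own, per the file headers. A library has the same values in each table that holds it. Whole reads were recovered by dividing a library's values by that value, and 100% of the values came out whole within 0.001 reads. The fewest reads over all libraries of any listed gene were 10. Of the gene IDs 16233 (98.8%) matched a reference table of names, and 50 genes share a symbol with another ID. Whether the counting used strand is not given in the sources used here, and reads shared by near-identical genes could not be split.

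Depth was 31860422 to 44988540 recovered reads per library. In simulated data with the means, library sizes and spread of these samples, limma recovered 77.6% of genes changed 2-fold and 35.8% of those changed 1.5-fold for Col2a1Cre;Idh1 fl/+ against Col2a1Cre (14617 genes, 9 false calls). It recovered 71.6% and 17.9% against Idh1 fl/+ (14797 genes, 9 false calls), and 74.6% and 29.9% between the controls (14756 genes, 14 false calls). For 4-fold changes the shares were 95.5%, 90.9% and 90.9%. In the same simulations camera found the list that had been shifted in each comparison and called 0 of 29 unshifted lists. The alternative test fry found it too, and called 0 of 29 unshifted lists against each control and 2 of 29 between the controls. The simulated genes varied independently, so these counts are no rates of false calls for the real libraries. There the other splits of the 6 libraries of Col2a1Cre;Idh1 fl/+ and Col2a1Cre called 7 to 13 lists by camera and 0 to 5 genes. With an estimated correlation the shifted list had an adjusted p of 0.0046, 0.0265 and 0.0893 for Col2a1Cre;Idh1 fl/+ against Col2a1Cre, against Idh1 fl/+ and between the controls. This list of independent genes was thus found in both comparisons of Col2a1Cre;Idh1 fl/+ and missed between the controls. It does not tell whether that test can find a real list whose genes vary together. The cholesterol list had an estimated correlation of 0.382 for Col2a1Cre;Idh1 fl/+ against Col2a1Cre.

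Before the data were examined the groups, tests, gene lists, rule for named genes and alternatives were fixed. Since the deposited values are normalized counts, the test foreseen for that case was used: limma with a mean-variance trend on log2(value + 1), two-sided, within each pair of groups, on genes with a value of at least 10 in at least as many libraries as the smaller group holds. Benjamini-Hochberg adjustment ran over all genes tested, and genes with an adjusted p under 0.05 were called. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. A fit of all 8 libraries compared Col2a1Cre;Idh1 fl/+ with the mean of the 2 control groups. Overlap between the comparisons was set against independent lists and against 50 simulations of unchanged groups. In these all 8 libraries were drawn around the control means, whereas the plan foresaw simulated controls against the Col2a1Cre;Idh1 fl/+ libraries. "Not overlapping" means that each library of a group lay above each of the other group.

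The 30 lists covered cholesterol biosynthesis, sterol uptake and SREBP control, fatty acid synthesis, cartilage matrix, hypertrophic chondrocytes, the Hedgehog pathway, Wnt targets, the tricarboxylic acid cycle, NADPH supply, glycolysis, hypoxia targets, alpha-ketoglutarate-dependent dioxygenases, the cell cycle, p53 targets, the interferon response, the unfolded protein and integrated stress response, immediate early genes, mitochondrially encoded and sex-linked genes, and markers of 11 other cell types. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry were alternatives. Lists of NRF2 targets, oestrogen receptor targets and further p53 targets were added after the data were seen and adjusted among themselves. Some genes stand in more than 1 list, such as Me1 and Atf3.

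Genes named per comparison were Idh1, up to 10 higher and 10 lower genes with the largest fold change among called genes whose groups did not overlap, with a mean of at least 100 and a symbol that is not a predicted-gene or clone name, up to 4 members of each list by lowest p, and the cholesterol biosynthesis genes. Values of some genes under this rule are not reported here, while the counts and tests of each list use all of its tested members. Where fewer than 5 genes qualified in a direction, the genes of lowest p were added up to 5 as values only. Phlda3, Grem1 and the other genes of the comparison of the controls came under this rule. A group value given for a gene named in another comparison comes from the same tables.

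Alternatives were a median-ratio rescaling, no filter, a floor of 50, pseudocounts of 0.5 and 5, DESeq2, edgeR and limma-voom on the recovered reads, all 8 libraries in 1 fit, an absolute log2 fold change of at least 1, an adjusted p under 0.1, the authors' deposited adjusted p and leaving out each library. Embryo sex as a covariate was added after the data were seen. Where a library left out leaves 1 in its group, that sample is assumed to vary like the other group. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.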

Results

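RNA was sequenced from primary sternal chondrocytes, the cartilage cells of the breastbone, taken from C57BL/6 mouse embryos at embryonic day 18.5. Col2a1Cre is a transgene that makes Cre recombinase under the control of Col2a1, the gene of the main cartilage collagen, and the floxed Idh1 allele carries sites at which Cre recombines DNA. Idh1 encodes the cytosolic isocitrate dehydrogenase, which makes alpha-ketoglutarate and NADPH. The series describes the cells as expressing a mutant Idh1. 3 libraries came from Col2a1Cre;Idh1 fl/+ cells (Cre-Idh1 cells in what follows), 3 from cells with Col2a1Cre and no floxed allele (the Cre control) and 2 from Idh1 fl/+ cells without Cre (the floxed control).

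The libraries held 31860422 to 44988540 reads assigned to the listed genes, and 16233 to 16363 of these genes had a read in a given library. Col2a1 was the most abundant gene in each of the 8 libraries and took 15.9% to 21.3% of the reads. Xist, the RNA of the inactive X chromosome, together with the Y-linked genes set apart female and male embryos: Cre-Idh1 replicate 1 and Cre control replicates 1 and 3 were female, and the other libraries were male. The 7 pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 10.3 to 84.2), so each was counted as a separate sample. The labels do not say whether the libraries of a group came from separate animals or litters. The Cre-Idh1 and Cre control groups each hold libraries of both sexes, so each came from more than 1 embryo. The p-values measure the spread between these samples, part of which may be technical. The first principal component of 15505 genes held 49.1% of the variance and set the 3 Cre-Idh1 libraries (-59.5 to -39.5) apart from the 5 controls (23.7 to 40.0). The second component (14.8%) set Cre-Idh1 replicate 3 (-43.3) apart from Cre-Idh1 replicates 1 and 2 (35.3 and 14.2).

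**Figure D1:**
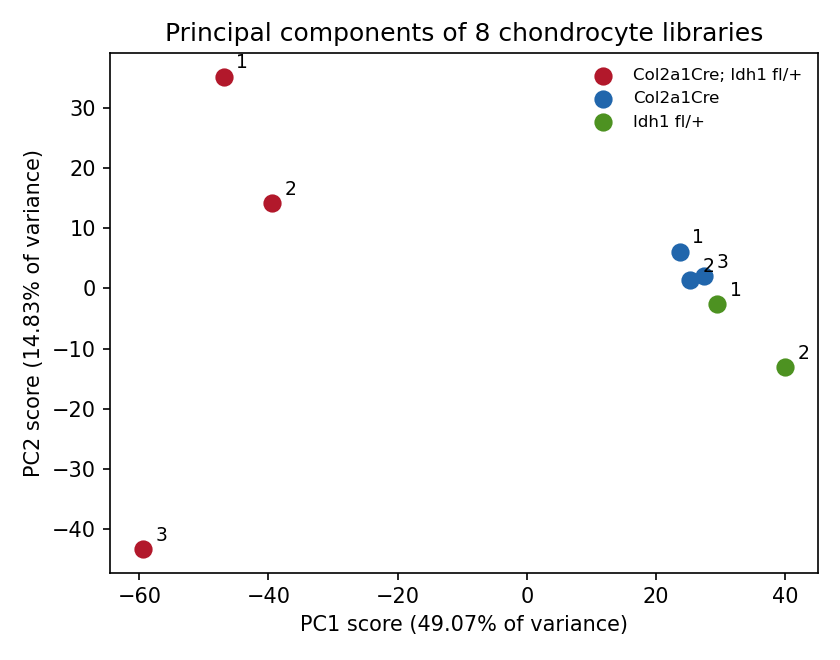
Principal components of log2(normalized count + 1) over 15505 genes, 1 point per library, coloured by group and labelled with the replicate number. The 3 Cre-Idh1 libraries lie between -59.5 and -39.5 on the first component and the 5 control libraries between 23.7 and 40.0.

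The modified gene was measured first. Idh1 stood at 3654 ± 258 normalized counts in Cre-Idh1 cells (SD, n = 3), at 3754 ± 205 in the Cre control (SD, n = 3) and at 2357 ± 133 in the floxed control (SD, n = 2). Total Idh1 RNA in Cre-Idh1 cells did not differ detectably from the Cre control (log2 fold change -0.04 ± 0.09, SE; limma adjusted p = 0.781) and was above the floxed control (0.63 ± 0.11; adjusted p = 0.0105, lost without floxed control replicate 1 or 2, up to 0.111, and with no scaling of the libraries, 0.0611). The floxed control lay below the Cre control (-0.67 ± 0.07) at a limma adjusted p of 0.0727. The libraries of these groups did not overlap for Idh1, as for 24.8% of the genes in this comparison, where chance gives 20%. The authors' deposited table gives an adjusted p of 4.35e-06 for this difference in Idh1. These values sum over both alleles and do not tell the mutant RNA from the normal one.

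**Figure D2:**
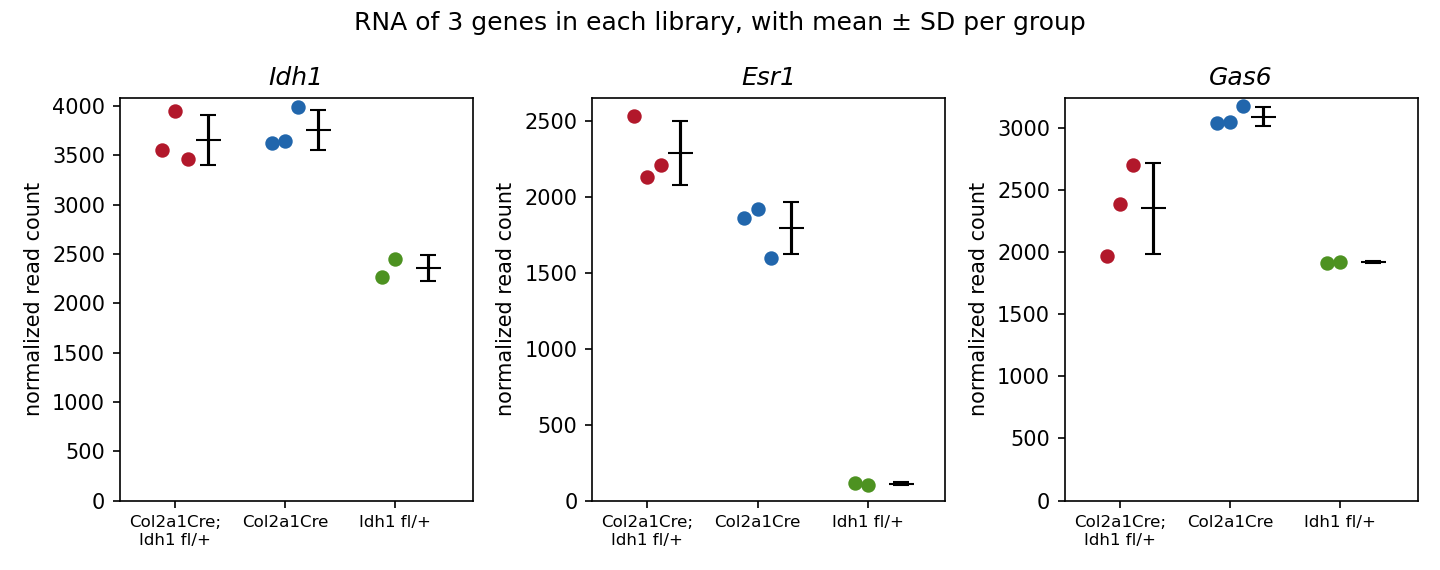
Normalized counts of Idh1, Esr1 and Gas6 in each of the 8 libraries, by group, with the mean and SD of each group. Esr1 lies near 111 in the floxed control and at 1794 and 2289 on average in the groups that carry Col2a1Cre.

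The comparison of Cre-Idh1 cells with the Cre control asks how chondrocytes described as expressing the mutant Idh1 differ from chondrocytes that carry the same Cre transgene. The enzymes of cholesterol synthesis rose almost throughout the pathway, and part of the genes of sterol uptake and of fatty acid synthesis rose as well. Several genes of the Hedgehog pathway, several cartilage and osteoblast genes and several glycolytic genes fell. Part of the p53 targets rose and part of the cell cycle genes fell. Of 14851 genes tested, 1455 rose and 1394 fell at a limma adjusted p under 0.05, and 556 of the risen and 294 of the fallen genes changed at least 2-fold. The libraries of the groups did not overlap for 41.0% of the genes, where chance gives 10%. The number called fell without Cre control replicate 1 (1603), replicate 2 (1404) or replicate 3 (1168), and with embryo sex as a covariate, a setting chosen after the data were seen (1898).

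Among the 21 genes of cholesterol biosynthesis, 18 rose and none fell over all genes tested, and 20 rose when adjusted over the list alone. Mvd, the mevalonate decarboxylase, went from 1044 ± 66.9 to 3313 ± 474 normalized counts (SD, n = 3 each; log2 fold change 1.66 ± 0.12, SE; adjusted p = 0.000132). Idi1 rose by 1.45 ± 0.18, and Lss, which closes the sterol rings, by 1.43 ± 0.10. Tm7sf2 (1.29), Hmgcs1 (1.19), Sc4mol (1.03), Acat2 (1.03), Hsd17b7 (0.97), Fdps (0.95), Fdft1 (0.91), Nsdhl (0.87), Dhcr7 (0.78), Cyp51 (0.77), Sc5d (0.72) and Sqle (0.71) also rose, as did Pmvk (0.74), whose call was lost without Cre control replicate 1, 2 or 3 (adjusted p up to 0.0810). Lbr (0.29, adjusted p = 0.0609), Mvk (0.42, 0.066) and Ebp (0.23, 0.173) did not pass. The list as a whole stood above the other genes (camera adjusted p = 1.02e-17), with an adjusted p of 0.385 with an estimated correlation. None of the 14 lists called here with the preset correlation held its call with an estimated one, and the same holds for the lists called in the other comparisons. Of these 14, fatty acid synthesis (fry adjusted p = 0.0514), cartilage (0.126), glycolysis (0.367), immediate early (0.126), macrophage (0.18) and osteoclast (0.163) also missed fry. The others passed fry, which does not compare a list with other genes. Over the splits of all 8 libraries into 3 and 5, 22 of 56 splits, the real one included, called at least as many lists as the real one, and 5 of 56 gave a lowest list p as small.

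**Figure D3:**
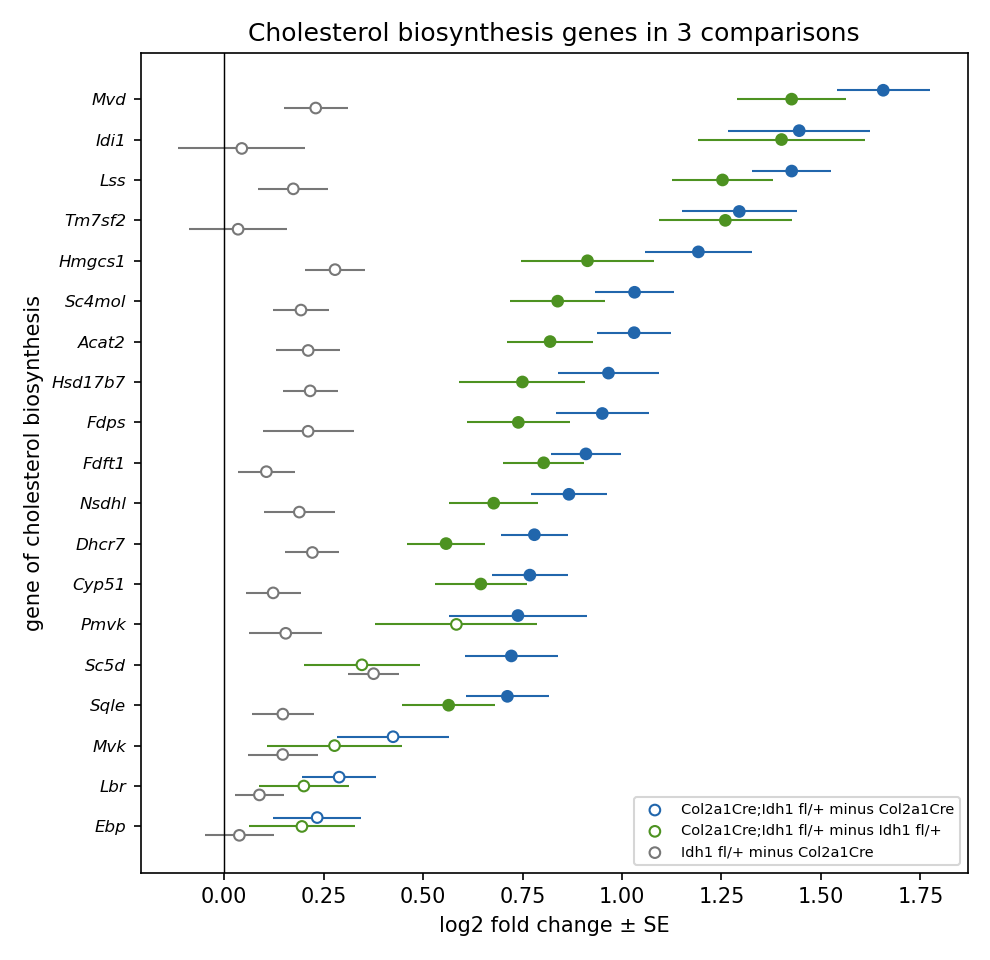
Log2 fold changes of 19 cholesterol biosynthesis genes in Cre-Idh1 cells against the Cre control (blue) and the floxed control (green), and in the floxed control against the Cre control (grey), with standard errors as bars. Filled points have a limma adjusted p under 0.05, which 16 of the genes drawn had against the Cre control and 14 against the floxed control.

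Of 21 genes of sterol uptake, efflux and SREBP control, 8 rose and 2 fell. Insig1, a brake on SREBP processing, rose by 1.19 ± 0.11 (SE). Cyp7b1, an oxysterol hydroxylase, changed by -1.09 ± 0.15. The list test did not pass (adjusted p = 0.052). In fatty acid synthesis 8 of 18 genes rose and 2 fell, 8 and 3 when adjusted over the list alone (camera adjusted p = 0.0164; adjusted p = 0.673 with an estimated correlation). Acss2, which makes acetyl-CoA from acetate, rose by 1.62 ± 0.16, Lpin1 by 0.87 ± 0.09, Acly by 0.77 ± 0.09 and Fasn, the fatty acid synthase, by 0.71 ± 0.09.

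Hedgehog signalling genes fell in 5 of 13 cases and none rose (camera adjusted p = 0.0118; adjusted p = 0.385 with an estimated correlation). Gli1, a transcriptional readout of the pathway, fell from 963 ± 39 to 436 ± 10.3 normalized counts (SD, n = 3; -1.14 ± 0.10), and the receptors Ptch1 (-0.72 ± 0.12) and Boc (-0.56 ± 0.09) and the factor Gli2 (-0.57 ± 0.10) fell with it. Of 24 genes of cartilage matrix and proliferating chondrocytes, 6 fell and 1 rose, 8 and 1 when adjusted over the list alone (camera adjusted p = 0.0445; adjusted p = 0.673 with an estimated correlation). The matrix protein gene Matn3 (-1.07 ± 0.10), Ucma (-0.70 ± 0.12) and Sox5 (-0.47 ± 0.09) fell, and the Wnt inhibitor Sfrp5 rose (1.21 ± 0.17). That list's call was lost without Cre-Idh1 replicate 1 (0.121) and without Cre control replicate 2 (0.0517). Among 16 genes of hypertrophic chondrocytes, the enlarged cells that precede bone, 5 fell, with Pth1r at -0.63 ± 0.10, and 1, Slc37a2 (1.43 ± 0.31), rose (up to 0.0606 without Cre control replicate 1 or 3), and the list did not pass (0.094). Osteoblast genes fell in 4 of 9 cases, among them Smpd3 (-1.13 ± 0.11) and Phex (-1.41 ± 0.27), with no call of the list (0.132). Perichondrial and fibroblast genes fell in 4 of 16 cases, among them Pdgfra (-0.99 ± 0.10) and Prrx1 (-0.92 ± 0.10), again without a call of the list (0.132). Of 15 Wnt targets 3 rose, such as Nkd2 (1.31 ± 0.27), and 2 fell, such as Tnfrsf19 (-1.24 ± 0.17), and the list did not pass (0.534).

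In glycolysis 5 of 18 genes fell, 6 when adjusted over the list alone, and none rose (camera adjusted p = 0.0412; adjusted p = 0.673 with an estimated correlation). The aldolase gene Aldoc fell by 1.54 and Pfkm, a phosphofructokinase, by 0.58 on the log2 scale, a call lost for Pfkm without Cre control replicate 2 or 3 (adjusted p up to 0.0737). The list's call was lost without Cre-Idh1 replicate 1 (0.0646) or 3 (0.0508) and without Cre control replicate 2 (0.275), a library in which the mean of the list lay 0.522 above the average of the 8 libraries. Among 18 hypoxia targets 1 rose, Ndrg1 (1.37 ± 0.26), and 2 fell, such as Car12 (-1.18 ± 0.14), and the list did not pass (0.151). The tricarboxylic acid cycle and isocitrate dehydrogenase list (3 of 21 fell, adjusted p = 0.348) and the alpha-ketoglutarate-dependent dioxygenases (1 of 29 rose and 3 fell, adjusted p = 0.397) did not pass either. Tet1, which oxidizes methylcytosine, was among the fallen dioxygenases (-1.19 ± 0.14). Genes of NADPH supply rose in 5 of 13 cases, 6 when adjusted over the list alone, with the thioredoxin reductase Txnrd1 at 0.62 ± 0.10 (camera adjusted p = 0.0459; adjusted p = 0.385 with an estimated correlation). That call was lost without Cre-Idh1 replicate 1 (0.0542) or 3 (0.0508) and without Cre control replicate 1 (0.0655).

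Of 16 p53 targets 7 rose and none fell (camera adjusted p = 0.00144; adjusted p = 0.385 with an estimated correlation). Gdf15, a secreted stress signal, rose by 1.27 ± 0.12, the pro-apoptotic Bbc3 by 0.76 ± 0.10, the cell cycle inhibitor Cdkn1a by 0.62 ± 0.09 and Perp by 0.72 ± 0.14. Of 24 further p53 targets, a list added later, 5 rose and 1 fell, 5 and 4 when adjusted over the list alone, and that list did not pass (mean log2 fold change 0.03, median -0.15, camera adjusted p = 0.991). Cell cycle genes fell in 5 of 24 cases, 9 when adjusted over the list alone, and none rose (camera adjusted p = 0.000455; adjusted p = 0.528 with an estimated correlation). Rrm2, which makes deoxynucleotides, fell by 0.80 and the mitotic kinase Plk1 by 0.51 on the log2 scale. Immediate early genes, which also respond to tissue digestion, rose in 6 of 21 cases, 7 when adjusted over the list alone, with Klf4 at 0.94 ± 0.08, Klf2 at 0.90 ± 0.12 and Fosl1 at 1.01 ± 0.15 (camera adjusted p = 0.00415; adjusted p = 0.673 with an estimated correlation). In the unfolded protein and integrated stress response 5 of 20 genes rose, such as Trib3 (1.08 ± 0.16) and Atf3 (0.70 ± 0.09), and 1 fell (camera adjusted p = 0.0459; adjusted p = 0.673 with an estimated correlation), a call lost without Cre-Idh1 replicate 2 (0.112) or 3 (0.0508) and without Cre control replicate 1 (0.056). The interferon list did not pass (1 of 14 fell, adjusted p = 0.95).

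Markers of other cells moved as well. Macrophage markers rose in 4 of 12 cases, 5 when adjusted over the list alone, with the complement gene C1qb at 2.25 ± 0.35 (camera adjusted p = 0.00415; adjusted p = 0.673 with an estimated correlation). The mean of that list lay at 1.37, 0.394 and 0.181 in the 3 Cre-Idh1 libraries against the average of the 8 libraries, and its call was lost without Cre-Idh1 replicate 1 (0.0542). The osteoclast (1 of 7 rose, 6 when adjusted over the list alone, camera adjusted p = 0.0236), keratinocyte (2 of 4 rose, with Dsp at 1.17 ± 0.23, adjusted p = 0.0459) and Schwann and neural lists (2 of 6 rose, adjusted p = 0.0147) were called too. With an estimated correlation their adjusted p were 0.673, 0.385 and 0.385, and the osteoclast call was lost without Cre-Idh1 replicate 1 (0.0646), the keratinocyte call without Cre-Idh1 replicate 1 (0.0542) or 3 (0.0600). The lists of endothelium (1 of 13 rose and 1 fell, adjusted p = 0.0561), skeletal muscle (2 of 10 rose and 1 fell, 0.542), neutrophils (2 of 11 fell, 0.83), adipocytes (1 of 5 rose, 0.395), erythroid cells (0 of 8, 0.206), the sex-linked genes (0 of 5, 0.507) and the mitochondrially encoded genes (2 of 7 rose and 1 fell, 0.52) did not pass.

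Most of the 20 largest changes named by the fixed rule lay outside these lists. Otog, known from the inner ear, rose from 16.4 ± 3.55 to 413 ± 70.8 normalized counts (SD, n = 3; log2 fold change 4.58 ± 0.23, SE; adjusted p = 4.12e-05). Kif1a, a kinesin of axonal transport, went from 24.8 ± 2.72 to 368 ± 39.3 (3.84 ± 0.19; adjusted p = 4.12e-05), and B4galnt2 (3.54 ± 0.21), Fibcd1 (3.41 ± 0.19), Asic4 (3.14 ± 0.36), Sstr2, a somatostatin receptor (2.97 ± 0.25), Cdsn (2.64 ± 0.18), Kcng1 (2.48 ± 0.25) and Angptl6 (2.30 ± 0.28) rose as well. Krt16 rose by 4.47 ± 0.29, which is uncertain because closely related keratin genes can share reads. Calml3, a calmodulin-like gene, fell from 920.2 ± 30.2 to 99.5 ± 27.1 normalized counts (-3.23 ± 0.18; adjusted p = 5.71e-05) and Tnnt3, a fast troponin T and member of the muscle list, from 1433 ± 42.2 to 217 ± 38.3 (-2.73 ± 0.14). Tspan8 (-2.67 ± 0.41), Otogl (-2.62 ± 0.37), As3mt (-2.46 ± 0.18), the ATP receptor P2rx7 (-2.32 ± 0.18), Pla2g5 (-2.10 ± 0.14), Cyp39a1 (-1.96 ± 0.13), Dsg2 (-1.93 ± 0.20) and Gjc3 (-1.92 ± 0.23) fell. Of the 123 named genes with a call in this comparison, 87 to 119 kept it when 1 library was left out, and 106 kept it with embryo sex as a covariate.

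The comparison with the floxed control asks the same of cells that carry the floxed allele without Cre. The lists of cholesterol synthesis, p53 targets and immediate early genes again stood higher in Cre-Idh1 cells, and those of Hedgehog, cartilage, glycolysis and cell cycle genes lower. Of 15212 genes tested, 1137 rose and 1059 fell, and 608 and 360 of them changed at least 2-fold. The libraries of the groups did not overlap for 53.4% of the genes, where chance gives 20%. With 2 control libraries the count rested on each of them: it fell to 592 without floxed control replicate 1 and to 186 without replicate 2, to 1432 and 1325 without Cre-Idh1 replicates 1 and 2, and reached 3752 without Cre-Idh1 replicate 3. It was 1434 with embryo sex as a covariate, chosen after the data were seen. Both floxed control libraries were male and only Cre-Idh1 replicate 1 was female, so this covariate amounts to leaving out that replicate. The 1434 is therefore no separate check on sex. The count was 3596 with all 8 libraries in 1 fit, 3554 at an adjusted p under 0.1 and 4095 by the adjusted p of the authors' deposited table.

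Of the 21 cholesterol genes 16 rose, 17 when adjusted over the list alone, and none fell (camera adjusted p = 5.02e-12; adjusted p = 0.529 with an estimated correlation). Mvd rose by 1.43 ± 0.14 (SE) and Lss by 1.25 ± 0.13. In sterol uptake 6 of 21 genes rose and 2 fell (adjusted p = 0.0898), and in fatty acid synthesis 4 of 18 rose, with Acss2 at 1.34 ± 0.16, and 2 fell (adjusted p = 0.326). Of the p53 targets 9 of 16 rose, 14 when adjusted over the list alone, with Gdf15 at 1.73 ± 0.14 and Cdkn1a at 16414 ± 699 normalized counts against 5863 ± 1262 (SD, n = 3 and 2) (camera adjusted p = 6.99e-08; adjusted p = 0.529 with an estimated correlation). Of the further p53 targets 6 of 24 rose, 8 when adjusted over the list alone (camera adjusted p = 0.000613; adjusted p = 0.325 with an estimated correlation). Immediate early genes rose in 9 of 21 cases, 13 when adjusted over the list alone, with Klf4 at 1.19 ± 0.10 and Fosl1 at 1.93 ± 0.18 (camera adjusted p = 1.26e-06; adjusted p = 0.529 with an estimated correlation). Cell cycle genes fell in 9 of 24 cases, 13 when adjusted over the list alone (camera adjusted p = 7.75e-06; adjusted p = 0.539 with an estimated correlation).

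Hedgehog genes fell in 4 of 13 cases, with Gli1 at -1.39 ± 0.13, and glycolytic genes in 7 of 18, with Slc16a3, a lactate exporter, at -1.62 ± 0.14, while 1 rose (camera adjusted p = 0.0128 and 0.000877). When adjusted over the list alone, 5 Hedgehog and 7 glycolytic genes fell. With an estimated correlation both had an adjusted p of 0.529. Of the cartilage genes 6 of 24 fell, with Matn3 at -1.20 ± 0.13, and 1 rose, of the hypertrophic genes 6 of 16 fell, with Pth1r at -0.97 ± 0.12, and 1 rose, and of the hypoxia targets 6 of 18 fell, while 1, Ndrg1 (1.55 ± 0.11), rose. When adjusted over the list alone, 7 genes of each of these lists fell. The camera adjusted p were 0.0113, 0.0446 and 0.0128, and each had an adjusted p of 0.568 with an estimated correlation. The hypertrophic call was lost without Cre-Idh1 replicate 2 (0.278) or floxed control replicate 1 (0.168). Osteoblast genes fell in 3 of 9 cases, with Smpd3 at -1.49 ± 0.11, and perichondrial genes in 4 of 16, with Prrx1 at -1.17 ± 0.12, without a call of either list (0.0677 and 0.0563). Macrophage markers rose in 5 of 14 cases (camera adjusted p = 0.000795), keratinocyte markers in 3 of 5 (0.0128) and osteoclast markers in none of 8, although that list was called upward (0.0296). With an estimated correlation their adjusted p were 0.568, 0.539 and 0.568, and without Cre-Idh1 replicate 3 the keratinocyte (0.0714) and osteoclast (0.0532) calls were lost, the latter also without replicate 1 (0.0676). The remaining lists did not pass, at adjusted p from 0.0563 (perichondrium) to 0.916 (Wnt targets).

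Among the genes that met the fixed rule, Otog (5.30 ± 0.37), Ostn, a bone-derived peptide hormone gene (4.67 ± 0.44), B4galnt2 (3.94 ± 0.25), Kif1a (3.43 ± 0.33), Fibcd1 (3.40 ± 0.20), Sstr2 (3.29 ± 0.22), Asic4 (3.11 ± 0.33) and Cdsn (2.86 ± 0.24) rose most, and Krt16 did so with the same uncertainty as above (4.58 ± 0.28). Esr1, the oestrogen receptor alpha gene, was higher by 4.35 ± 0.13 than in the floxed control. Calml3 (-3.04 ± 0.24), Tnnt3 (-2.97 ± 0.17), As3mt (-2.64 ± 0.22), the deiodinase gene Dio2 (-2.61 ± 0.17) and Cyp39a1 (-2.33 ± 0.17) were among the 10 that fell most under the fixed rule. Of the 112 named genes with a call in this comparison, 54 kept it without floxed control replicate 1 and 34 without replicate 2, against 93 to 110 without a Cre-Idh1 library.

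Among the 14813 genes tested against both controls, 946 rose and 921 fell in both comparisons, and none moved in opposite directions. Independent lists of these sizes would share 111 risen and 98.2 fallen genes. Both comparisons use the same Cre-Idh1 libraries. In 50 simulations of unchanged groups 0.06 genes were shared on average and 1 at most. Those simulations called on average 0.26 risen and 0.3 fallen genes against the Cre control and 0.58 and 0.14 against the floxed control. With so few calls almost none can be shared, so this number is no measure for the genes shared here. The simulations also had 0 genes in opposite directions on average. Shared libraries make opposite calls unlikely, so their absence says little. The fold changes correlated across genes, which are not independent replicates, at r = 0.895, against 0.464 in the simulations, and their covariance was 0.341 against 0.0328. The 3 shared libraries are too few to be split, so part of the excess over these values may come from the shared libraries. The number shared fell to 554 without floxed control replicate 1 and to 186 without replicate 2, to 1243 and 1178 without Cre-Idh1 replicates 1 and 2 and to 1212 and 1058 without Cre control replicates 2 and 3, and was 2891 without Cre-Idh1 replicate 3. A fit of all 8 libraries against the mean of the 2 control groups called 4845 of 15505 genes, 2367 risen and 2478 fallen, and 1220 of these changed at least 2-fold. The Cre-Idh1 libraries did not overlap the 5 control libraries for 35.4% of the genes, where chance gives 3.57%. The number called in this fit was 3073 without floxed control replicate 2.

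**Figure D4:**
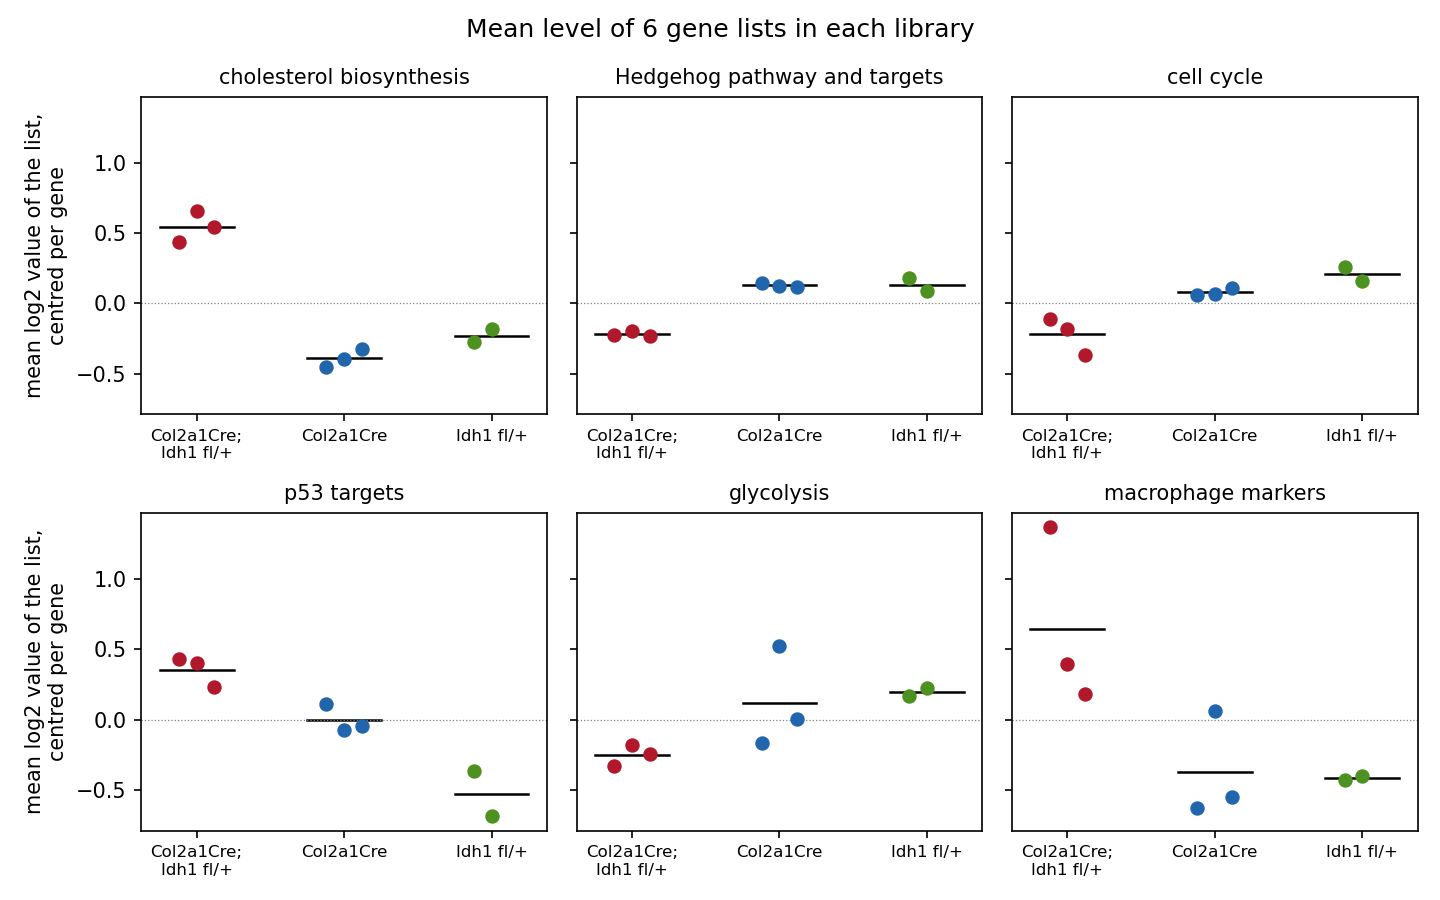
Mean of 6 gene lists in each of the 8 libraries, as log2(normalized count + 1) centred per gene over the libraries, with a black line at each group mean. The cholesterol biosynthesis mean lies at 0.434 to 0.653 in the Cre-Idh1 libraries and below 0 in the 5 controls, and the p53 mean at -0.684 and -0.365 in the floxed control.

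The controls were compared to ask how the Cre transgene and the floxed allele differ on their own. Esr1 and Gas6 were called, both lower in the floxed control, among 14870 genes tested with limma. Esr1 stood at 111 ± 8.47 normalized counts in the floxed control (SD, n = 2) and at 1794 ± 172 in the Cre control (SD, n = 3), a log2 fold change of -4.00 ± 0.11 (SE; adjusted p = 4.28e-06), and that call held without any 1 library. Cre-Idh1 cells, which also carry Col2a1Cre, had 2289 ± 212. Gas6, a ligand of the TAM receptors, lay at 1915 ± 9.43 against 3086 ± 76.5 (-0.69 ± 0.06; adjusted p = 0.0239), and that call was lost without Cre control replicate 1 or 3 or floxed control replicate 2 (up to 0.405), with all 8 libraries in 1 fit (0.318) and with embryo sex as a covariate (0.641). With that covariate the difference rests on the 2 floxed control libraries against Cre control replicate 2, the only male Cre control library. The lost Gas6 call thus does not tell an effect of sex from fewer samples. The Esr1 and Gas6 values are totals over each gene, with no read positions. At an unadjusted p under 0.05 there were 1133 genes where chance gives 744, edgeR called 2 genes, DESeq2 called 86, and 36 passed in the authors' deposited table. The limma count was 102 without floxed control replicate 1, 8 without Cre control replicate 2 and 1 without Cre control replicate 1 or 3 or floxed control replicate 2. The genes of lowest p beyond these were not called: Sc5d had a log2 fold change of 0.38 ± 0.06, Dio2 of 0.69 ± 0.13, Grem1 of 0.87 ± 0.17, Cd24a of 0.40 ± 0.07, Gpnmb of -0.64 ± 0.08 and Plcd4 of -1.27 ± 0.17 (adjusted p = 0.101 for Gpnmb and 0.181 for Plcd4).

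No member of any list passed over all genes in this comparison, but 10 lists shifted as a whole by camera (6 without Cre control replicate 3 or floxed control replicate 1). The p53 targets were lower in the floxed control (median -0.46, camera adjusted p = 4.05e-18; adjusted p = 0.599 with an estimated correlation), and 14 of 16 had a lower value when adjusted over the list alone. Cdkn1a had a log2 fold change of -0.88 ± 0.13 (SE; adjusted p over all genes = 0.189) and Phlda3 of -0.93 ± 0.16. Immediate early genes were lower (median -0.22, 4.16e-07), a call lost without floxed control replicate 2 (0.0803), and cholesterol biosynthesis (median 0.15, 6.31e-09), fatty acid synthesis (median 0.12, 9.84e-05) and the cell cycle (median 0.16, 1.53e-05; 0.127 without floxed control replicate 1) were higher. Cartilage (0.0389), hypertrophic (0.0157), osteoblast (0.0275), perichondrial (0.0275) and sex-linked (0.041) lists were called higher. When adjusted over the list alone, 4 cell cycle genes, 2 perichondrial genes, 1 cholesterol gene and 1 hypertrophic gene were higher and 1 immediate early gene lower, and of the 5 sex-linked genes 4 were higher and 1 lower, where both floxed control libraries and Cre control replicate 2 were male. With an estimated correlation the adjusted p was 0.796 for the perichondrial list and 0.599 for the other 9. Without floxed control replicate 1 the cartilage (0.205), hypertrophic (0.820), osteoblast (0.810) and sex-linked (0.170) calls were lost, and without its replicate 2 the perichondrial call (0.226). Without Cre control replicate 1 the cartilage (0.0885), osteoblast (0.0835), perichondrial (0.526) and sex-linked (0.118) calls were lost, without replicate 2 the cartilage call (0.0670), and without replicate 3 the cartilage (0.0874), hypertrophic (0.0874), osteoblast (0.128) and sex-linked (0.137) calls. The fry test, which asks whether the genes of a list move one way on balance and does not compare them with other genes, called none of the 30 lists here, against 9 in the comparison of Cre-Idh1 cells with the Cre control and 6 with the floxed control.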

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

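The sex covariate was chosen after the data were seen, and all other alternatives before. Against the floxed control it amounts to leaving out Cre-Idh1 replicate 1, the only female library there. Between the controls it sets the 2 floxed control libraries against Cre control replicate 2, the only male Cre control library. Calls of Cre-Idh1 cells against the Cre control, 2849 in number, stayed within 1.5 times of that count with another scaling, filter, pseudocount, tool or the authors' adjusted p, and were 850 at an absolute log2 fold change of at least 1 and 1898 with embryo sex as a covariate. Leaving out 1 library gave 1168 (without Cre control replicate 3) to 3854 (without Cre-Idh1 replicate 3). Against the floxed control the 2196 calls became 3596 with all 8 libraries in 1 fit, 968 at an absolute log2 fold change of at least 1, 3554 at an adjusted p under 0.1, 4095 by the authors' adjusted p and 1434 with the sex covariate, and ranged from 186 (without floxed control replicate 2) to 3752 (without Cre-Idh1 replicate 3). The 2 calls between the controls became 86 with DESeq2, 36 by the authors' adjusted p, and 1, Esr1, with all 8 libraries in 1 fit, at an absolute log2 fold change of at least 1 or with the sex covariate. Leaving out 1 library gave 1 to 102 (without floxed control replicate 1). The 1867 genes shared by both comparisons were 2678 in 1 fit and 2524 with DESeq2, and ranged from 186 (without floxed control replicate 2) to 2891 (without Cre-Idh1 replicate 3). The 4845 calls against both controls were 5058 with the controls as 1 group, 4532 with the sex covariate and 3073 (without floxed control replicate 2) to 5229 without 1 library. A stricter threshold gives smaller counts by construction. Fewer samples did not always do so, since 3854 genes were called against the Cre control without Cre-Idh1 replicate 3. Apart from the threshold, the cause of these changes was not tested.

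The 14, 12 and 10 called lists were 0, 0 and 0 with an estimated correlation and 9, 6 and 0 with fry. Without 1 library they ranged from 10 to 17, 12 to 16 and 6 to 12. Without floxed control replicate 2 the Schwann and neural list turned its direction between the controls and was called (adjusted p = 0.012, against up to 0.798 without any other library). The Idh1 difference from the floxed control was 0.48 with no scaling of the libraries (adjusted p = 0.0611); the cause was not tested. No named gene with a call turned its direction in any alternative. No paired analysis was possible because the replicate numbers follow the order of the records. Depth was 31860422 to 44988540 reads per library, and in the comparisons that use the floxed control the counts of called genes moved most when 1 of its 2 libraries was left out.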

Other observations

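Part of a list of genes that answer to NRF2, the transcription factor of the oxidative stress response, rose in Cre-Idh1 cells. The list of 20 was written after some results had been seen, and 4 known targets whose values had been seen were left out, 1 of them after a first run of the test. Gsr, G6pdx and Slc7a11, members of fixed lists that had been tested, stayed in. The p-values of this list are thus no test on unseen genes. Against the Cre control 10 of 19 tested genes rose, 11 when adjusted over the list alone, and none fell (camera adjusted p = 1.31e-06 over 3 added lists; adjusted p = 0.327 with an estimated correlation). The ferritin gene Fth1 rose by 0.76 ± 0.10 (SE), the peroxiredoxin gene Prdx1 by 0.74 ± 0.09, the glutathione synthesis gene Gclc by 0.78 ± 0.11, Osgin1 by 1.08 ± 0.19 and Gsta4 by 1.49 ± 0.27. Against the floxed control 10 rose, 12 when adjusted over the list alone, with Fth1 at 1.05 ± 0.13, Gclc at 1.07 ± 0.13 and Osgin1 at 1.58 ± 0.25 (camera adjusted p = 1.26e-06; 0.325 with an estimated correlation). Between the controls no member passed and the list was lower in the floxed control (0.0032; 0.211 with an estimated correlation).

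The tests of sex, other cells, scaling, the floxed allele, the presence and sequence of the transgene and dissociation stress below and the split tests of the cholesterol list and of the strongest list were chosen after the values they weigh had been seen, and the tests of neighbouring genes, of oestrogen receptor targets, of further p53 targets and of the counts of genes and lists over other splits before. Esr1 RNA was high in the 6 libraries with Col2a1Cre and low in the 2 without, and sex does not account for it, since the lowest male library with Col2a1Cre had 16.4 times the highest floxed control value. Neither does a broad loss of macrophage, endothelial, perichondrial or osteoblast RNA, since the lowest median change among their markers was -0.14. Other cell types were not weighed in this way, and keratinocyte markers had a median of -0.27. A region-wide change does not account for it either. The 10 measured neighbours of Esr1 in the reference gene order had a median absolute log2 fold change of 0.0559. Oestrogen receptor targets, some of them also in other lists (Xbp1, Ccnd1, Car12 and Ltf), had a mean log2 fold change of -0.12 with 7 of 18 above 0 and 0 called over the list alone. Members that go both ways decide nothing, although a mean above -0.3 with no call had been set in advance as evidence against it, so a change of receptor activity stays open. Another candidate explanation left open is receptor sequence carried by the Cre transgene, as in hormone-inducible forms of Cre: the lowest library with Col2a1Cre had 13.6 times the highest floxed control value, and read positions along the gene, not used here, would be needed to tell it from the endogenous gene.

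Idh1 RNA was lower in the floxed control than in the Cre control. Scaling does not account for it, since the ratio came no nearer to 1 than 0.688 under the other scalings, and neither does sex, since the lowest male library with Col2a1Cre had 1.41 times the highest floxed control value, against 1.08 times between the 2 floxed control libraries. The 10 measured neighbours of Idh1 had a median log2 fold change of -0.0484, against a change of the whole region. The ratio of 0.628, with Cre-Idh1 cells at the level of the Cre control, may reflect less RNA from the floxed allele before Cre acts on it, and this cannot be told apart from other differences between the groups, since no library carries a floxed allele that is known to be intact in the presence of Cre.

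The p53 targets were lower in the floxed control than in the Cre control, and further p53 targets outside the fixed list had a mean log2 fold change of -0.37, with 23 of 24 below 0 and 11 lower when adjusted over the list alone (camera adjusted p = 1.88e-16; 0.208 with an estimated correlation). In Cre-Idh1 cells against the Cre control, where the fixed list was called higher, the further targets had a mean of 0.03 and a median of -0.15, with 14 of 24 below 0 (camera adjusted p = 0.991), and against the floxed control a mean of 0.40 (0.000613; 0.325 with an estimated correlation). Sex stays open for the difference between the controls. The only male Cre control library lay 0.290 (log2 list mean) above the highest floxed control library, less than the 0.319 between the 2 floxed control libraries. A gap of more than 0.1 had been written down as evidence against sex, after the values were seen, and the gap met it. It rests on 1 male Cre control library and lies within the spread of the floxed control, so it is not taken to decide. Dissociation stress stays open too, since the immediate early list also had a median of -0.22 between the controls. The mean of that list lay at -0.053 and -0.635 in floxed control replicates 1 and 2, against -0.189 to 0.092 in the Cre control. Replicate 1 had low p53 targets (-0.365, against -0.075 to 0.108 in the Cre control) without low immediate early genes. That is 1 library and does not decide. Presence of Cre recombinase cannot be told apart from the other differences between the groups: the p53 targets lay 0.92 (median log2 fold change) higher in Cre-Idh1 cells than in the floxed control, but this value rests on the same 2 floxed control libraries and decides nothing.

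Other splits of the same libraries were tested for the counts of calls and for the p of the lists. For Cre-Idh1 against the Cre control the 10 splits of 6 libraries are too few for a share under 0.05: the real split called 2849 genes and the highest other 5, 14 lists against 13, and gave cholesterol biosynthesis a camera p of 3.41e-19 against 2.47e-09, and 1 of the 10 splits reached each of these values. The lowest camera p over all lists was as small in 2 of the 10 (3.41e-19, lowest other 2.62e-21). For Cre-Idh1 against the 5 controls as 1 group, 1 of 56 splits called as many genes (5058, highest other 5). That share (0.0179) is the smallest that 56 splits can give, and it lies under the 0.05 set in advance. It makes a chance split an unlikely source of the count only if the libraries are exchangeable. The labels do not settle this, since they do not say whether libraries of a group share an animal or litter. Chance cannot be excluded for the number of lists (10, highest other 14, 22 of 56 splits). For the cholesterol list 2 of 56 splits gave a camera p as small (5.67e-17, lowest other 5.03e-19), and the other of these splits set the 3 Cre control libraries apart from the rest. That share leaves out that this list had the lowest p of the 30. With the lowest camera p over all lists in each split, 5 of 56 splits were as small (lowest other 4.11e-22), 1 of them the split of the 3 female libraries from the male ones, so chance cannot be excluded for the list test.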
